A study of Mus musculus with 16 samples.

How the data were processed

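The series holds 16 RNA-seq libraries of mouse retina in 4 groups, each library from 1 file, and each library was placed in its group by its label for the eye (crushed or uncrushed) and for the drug (control, which is the vehicle, or DLKi, which is the inhibitor GNE-3511). Replicates were numbered in the order of the records and such a number pairs nothing. Per the labels' protocols, the mice were studied 3 days after the injury, RNA was extracted with a column kit and DNase digestion, 0.5 µg of total RNA per sample went into poly(A) libraries made with the TruSeq RNA kit version 2, and these were sequenced on a HiSeq4000 as single reads of 50 bases, 30 M reads being stated per library. The labels state 5 mice per drug; 5 crushed and 5 uncrushed inhibitor retinas and 3 crushed and 3 uncrushed vehicle retinas were given, and other vehicle retinas were not analysed here. The labels do not say which retinas share an animal, so p-values measure the spread between these samples.

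The authors' deposited counts are, per the file headers, whole numbers of reads aligned uniquely to each gene model, listed by Entrez identifier. The aligner was GSNAP and the genome build GRCm38, per the submitters' processing notes; the aligner's version, its settings and the annotation release are not given in the sources used here. The files also hold, per the file headers, the authors' nRPKM, an RPKM value scaled by a size factor per library; how that factor was made is not given in the sources used here. Across genes the ratio of nRPKM to count differed between libraries by a constant factor, to a relative spread of 1.84e-14, so nRPKM holds no correction beyond gene length and library. Counts were used for every test, and nRPKM only to give levels as mean ± SD. Unique alignment lowers the counts of genes with near-identical copies, and the kit does not mark strand, so reads of overlapping genes on opposite strands cannot be told apart; among 84 genes checked against the GENCODE annotation of the same build, 23 had some exon overlap with another gene and 2, Alkal2 and Jund, had more than 25% of their exon length overlapped.

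Of 36528 identifiers, 31049 matched a symbol in the RefSeq annotation of GRCm38, which also gave the coordinates; the 5479 without one held 1.098% to 1.216% of the counts. Total counts were 22.35 to 44.75 M per library, scaling factors 0.9729 to 1.024, rhodopsin 3.078% to 4.285% and mitochondrial genes 2.021% to 4.539% of the counts. No 2 replicates were copies of one library: over genes with a summed count of at least 20 the chi-square per degree of freedom between replicates was 6.75 to 42.9.

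Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalisation, filterByExpr over the 4 groups, quasi-likelihood fit and F test) on all 16 libraries with a mean per group and no covariate, so that the groups shared an estimate of the spread with 12 residual and 5.27 prior degrees of freedom. The filter left 19391 genes. The 5 contrasts were crushed against uncrushed with vehicle, the same with the inhibitor, inhibitor against vehicle in crushed and in uncrushed retina, and the difference of the crush effects. Every adjusted p of a gene is Benjamini-Hochberg adjusted over all tested genes of a contrast, and a gene is called at 0.05 or less; SE are those of the log2 change from this fit. All tests were two-sided.

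The contrasts, the alternatives, 33 gene lists with 500 genes and the rule for named genes were chosen before the data were examined. The lists cover ATF4 and integrated stress response targets, aminoacyl-tRNA synthetases, IRE1-XBP1 and ATF6 targets, heat shock, DLK-JNK pathway, immediate early, axon injury, pro-apoptotic and p53 target genes, markers of retinal cell types (ganglion, rod, cone, bipolar, amacrine, horizontal, Müller glia), gliosis, microglia, leukocyte, interferon, complement and chemokine genes, markers of neighbouring tissues (endothelium, pigment epithelium, lens, muscle, oligodendrocytes, blood) and cholesterol, oxidative phosphorylation, drug-response, clock and glucocorticoid genes. Each was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a contrast, and again with an estimated correlation. The estimate for ganglion cell markers in the crush effect with vehicle was 0.755. For lists whose genes vary together so closely, p-values at the preset correlation are too small. A list's score in a library is the mean log2 CPM of its measured genes. Named were, in each contrast, Map3k12 and Map3k13; the 8 largest increases and 8 largest decreases among called genes with a mean of at least 1 CPM and a proper symbol (5 and 5 for the crush effect with inhibitor and the inhibitor effect in uncrushed retina); and from each list up to 4 called members with the smallest p, or up to 2 where none was called. A further 6 lists were chosen after the data were seen.

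The tests were run on simulated counts with the means, depths and spread of these libraries. In them 67, 67 and 66 genes with a mean of at least 1 CPM were changed by 1.5, 2 and 4-fold. Libraries were drawn independently of each other, so recovery was not measured for genes with lower counts or for libraries that vary together. With the design of the crush effect with vehicle, edgeR recovered 61.2%, 97% and 100% of them among 19206 genes; with that of the crush effect with inhibitor 74.6%, 95.5% and 100% over 19189; of the inhibitor effect in crushed retina 71.6%, 86.6% and 100% over 19177; in uncrushed retina 70.1%, 98.5% and 97% over 19170; and of the difference of crush effects 43.3%, 85.1% and 98.5% over 19185. Unchanged genes called numbered 9, 7, 9, 13 and 7.

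For the size of the crush response, genes called by the average of both crush effects were compared between treatments and with 50 simulations of equal effects. Alternatives were the RLE size factors of edgeR in place of TMM, no filter on low counts, the DESeq2 1.42.0 Wald test, limma-voom, a fit of the compared groups only, a minimum log2 change of 0.5, pairs of consecutive library numbers as a replicate block, leaving out each library in turn, and leaving out the vehicle pair whose numbers stand apart. Leaving out the pair of shallowest vehicle libraries (crushed replicate 3 and uncrushed replicate 1), leaving out the 3 libraries with most lens transcripts (uncrushed vehicle replicate 2, uncrushed DLKi replicates 3 and 5), and thinning counts to the shallowest library were added after seeing the data. Lists were also tested with fry. Alternatives that apply only to files without counts were not needed. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.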

Results

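Gene expression was measured in mouse retina 3 days after optic nerve crush, an injury that severs the axons of retinal ganglion cells, the neurons that carry the output of the retina to the brain. Mice were given vehicle or GNE-3511, an inhibitor of dual leucine zipper kinase (DLK), a kinase that relays axon damage to the nucleus of the neuron. The inhibitor was dosed at 75 mg/kg at 60 h and again at 68 h after the crush. The first 60 h of the response therefore ran without it, and the comparisons below cannot show what earlier dosing would change. The 16 poly(A) RNA libraries fell into 4 groups: uncrushed vehicle (n = 3), crushed vehicle (n = 3), uncrushed inhibitor (uncrushed DLKi, n = 5) and crushed inhibitor (crushed DLKi, n = 5). The labels state 5 mice for each drug, and any further vehicle retinas were not analysed here. The libraries held 22.4 to 44.7 M counted reads, with group means of 32.1, 30.5, 37.5 and 34.3 M in the order above. Each had 23939 to 24609 genes with at least 1 read. The first principal component held 23.7% of the variance and placed all 8 crushed libraries, at -32.4 to -6.92, below all 8 uncrushed ones, at 11.2 to 31.6. The second held 17.3% and set 2 vehicle libraries apart, uncrushed replicate 1 at -49.4 and crushed replicate 3 at -34.3, against -17 to 23.1 for the others. These 2 were also the shallowest, and uncrushed vehicle replicate 1 had 4.539% mitochondrial counts, against at most 3.133% elsewhere.

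Transcripts of the drug's target did not differ measurably between the groups. Map3k12, which encodes DLK (Entrez 26404, GRCm38 chromosome 15, 102497647 to 102517004), stood at 41.5 ± 5.01 nRPKM in uncrushed vehicle, 39.9 ± 3.43 in crushed vehicle, 40.5 ± 1.57 in uncrushed DLKi and 39.4 ± 1.23 in crushed DLKi retina (SD, n = 3, 3, 5 and 5). Map3k13, which encodes the related leucine zipper kinase LZK, stood at 4.90 ± 0.57, 5.01 ± 0.475, 5.12 ± 0.369 and 5.22 ± 0.539 nRPKM in the same order. The lowest adjusted p of either gene in any of the 4 pairwise contrasts was 0.765, for Map3k13 between the uncrushed groups (edgeR quasi-likelihood test, Benjamini-Hochberg). Exons of Pcbp2, on the other strand, overlap 17.5% of the exon length of Map3k12. The kit does not mark strand, so the level given for Map3k12 may include reads of Pcbp2.

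The first comparison asked how the retina responded to crush without the inhibitor, in 3 crushed against 3 uncrushed vehicle retinas. Genes known to be induced in damaged neurons were among the largest increases that the naming rule admits (a mean of at least 1 CPM and a proper symbol). Sprr1a, a small proline-rich protein of axotomised neurons (Entrez 20753, GRCm38 chromosome 3, 92483954 to 92485881), stood at 0.182 ± 0.138 nRPKM in uncrushed and 24.9 ± 4.25 in crushed retina (SD, n = 3 each), a log2 change of 7.25 ± 0.39 (SE; edgeR quasi-likelihood adjusted p = 3e-09). Ecel1, a neuronal membrane protease induced by nerve injury (Entrez 13599, GRCm38 chromosome 1, 87142874 to 87157085), rose from 0.155 ± 0.048 to 10.1 ± 3.21 nRPKM (log2 change 5.97 ± 0.27, adjusted p = 2.67e-10). Atf3, a stress-induced transcription factor of injured neurons (Entrez 11910, GRCm38 chromosome 1, 191170296 to 191183333), rose from 3.15 ± 0.302 to 21.6 ± 1.53 nRPKM (2.78 ± 0.21, adjusted p = 4.65e-07). Sox11, a transcription factor of growing neurons, rose from 0.279 ± 0.037 to 2.39 ± 0.344 (3.09 ± 0.23, adjusted p = 4.65e-07). Among the other increases named by this rule were the macrophage elastase gene Mmp12 (5.72 ± 0.26), the interferon-induced chemokine gene Cxcl10 (3.99 ± 0.52), the pro-apoptotic BH3-only gene Hrk (3.21 ± 0.15) and the prostaglandin F receptor gene Ptgfr (2.75 ± 0.53), with adjusted p between 2.67e-10 and 0.00633. Of 25 measured axon injury and regeneration-associated genes, 13 rose and 0 fell (17 adjusted over the list alone; camera adjusted p = 1.11e-75, adjusted p = 0.000171 with an estimated correlation).

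**Figure D1:**
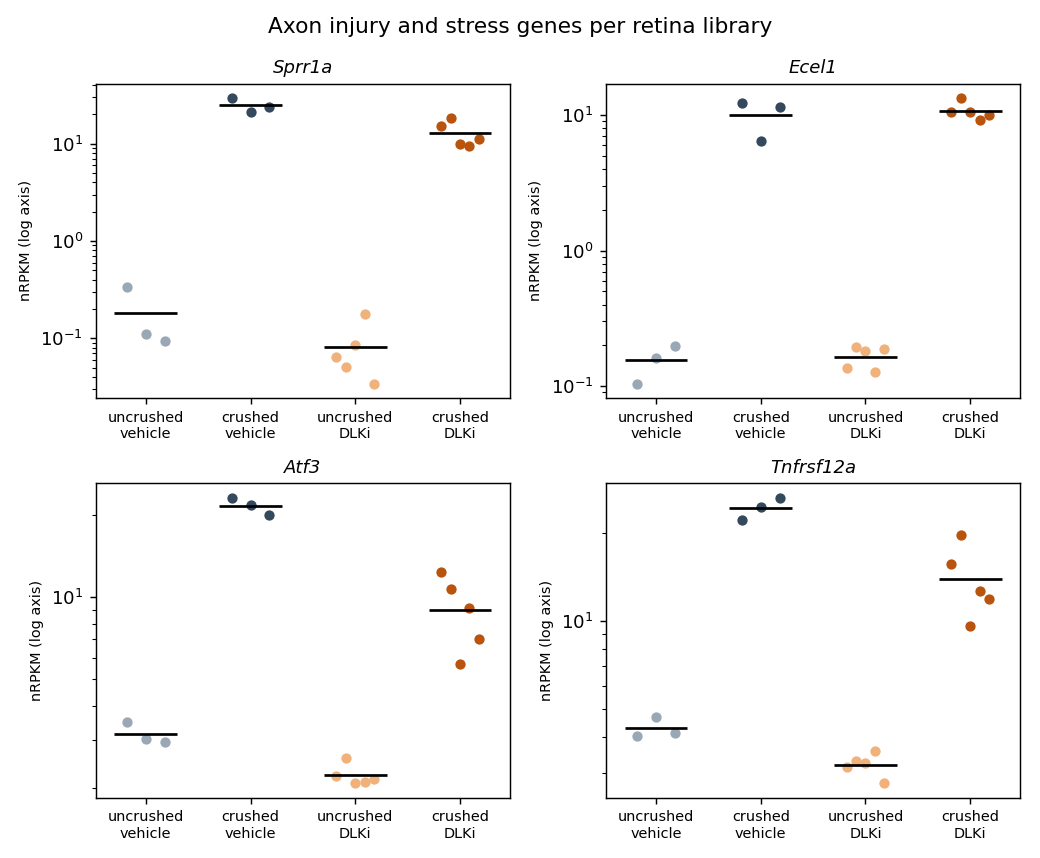
Sprr1a, Ecel1, Atf3 and Tnfrsf12a in the 16 retinas, as deposited nRPKM on a log axis (each point is 1 library, each line a group mean; n = 3 per vehicle and 5 per DLKi group). Atf3 spans 20.04 to 23.1 nRPKM in crushed vehicle and 5.715 to 12.37 in crushed DLKi retina, while Ecel1 spans 6.425 to 12.33 and 9.159 to 13.42.

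Stress and cell death genes rose with them. Of 32 measured targets of ATF4, the transcription factor of the integrated stress response, 17 rose and 0 fell (24 adjusted over the list alone; camera adjusted p = 3.08e-43, adjusted p = 0.000735 with an estimated correlation). Chac1, a glutathione-degrading enzyme induced by ATF4, rose from 2.34 ± 0.223 to 9.17 ± 1.39 nRPKM (log2 change 1.97 ± 0.20, edgeR quasi-likelihood adjusted p = 1.35e-05). Atf5 rose from 13.0 to 24.8 (0.94 ± 0.11) and Ddit3, encoding CHOP, from 20.1 to 33.0 (0.72 ± 0.09). Of 20 cytosolic aminoacyl-tRNA synthetase genes, 7 rose (13 adjusted over the list alone; camera adjusted p = 3.35e-13). The amounts were small, such as 0.49 ± 0.09 for Gars, 0.43 ± 0.09 for Nars, 0.34 ± 0.07 for Tars and 0.31 ± 0.07 for Lars. Of 18 immediate early genes, 6 rose (12 adjusted over the list alone; camera adjusted p = 2.74e-14). Jun, the main nuclear target of the DLK pathway, rose from 11.0 ± 1.9 to 21.6 ± 2.96 nRPKM (0.97 ± 0.17, adjusted p = 0.00238), beside Fosb (1.03 ± 0.17), Fosl2 (0.80 ± 0.17) and Egr2 (2.81 ± 0.50). Levels of Egr2 were very low, at 0.02 ± 0.009 nRPKM in uncrushed and 0.137 ± 0.03 in crushed vehicle retina. Of 19 pro-apoptotic genes, 3 rose (5 adjusted over the list alone; camera adjusted p = 2.6e-09), namely Hrk, Bbc3 (0.93 ± 0.16) and Bcl2l11 (0.53 ± 0.12). Among 14 p53 targets only Cdkn1a, the cell cycle inhibitor p21, rose, from 2.23 ± 0.449 to 8.24 ± 0.554 nRPKM (1.87 ± 0.16, adjusted p = 2.21e-06). The list's camera adjusted p was 0.00586, and its adjusted p = 0.0507 with an estimated correlation. The co-chaperone gene Bag3 was the 1 of 13 heat shock genes that rose (0.75 ± 0.15; list adjusted p = 0.142). Calls of Nars (without crushed vehicle replicate 2), Fosl2 and Bag3 (replicate 1), Lars (crushed vehicle replicate 1, uncrushed 2), Tars (crushed 1 and 2, uncrushed 2) and Bcl2l11 (crushed 1 and 3, uncrushed 2 and 3) were lost in fits without those vehicle libraries, at adjusted p up to 0.0688, 0.0897, 0.063, 0.1, 0.0608 and 0.122. The p53 list was lost without crushed vehicle replicate 2 (0.0819).

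Markers of retinal ganglion cells fell. Of 19 measured markers 12 fell and 0 rose (16 adjusted over the list alone; camera adjusted p = 5.66e-46, adjusted p = 0.00959 with an estimated correlation). Rbpms2, an RNA-binding protein of these cells, fell from 9.82 ± 1.86 to 3.12 ± 0.902 nRPKM (log2 change -1.65 ± 0.17, edgeR quasi-likelihood adjusted p = 2.16e-05). Nefh, the heavy neurofilament subunit of large axons, fell from 27.9 ± 4.55 to 10.1 ± 3.3 (-1.46 ± 0.17). The LIM-homeodomain factor gene Isl2 fell from 1.75 ± 0.434 to 0.535 ± 0.179 (-1.70 ± 0.21) and the nicotinic receptor subunit gene Chrna6 from 32.8 ± 8.01 to 12.2 ± 2.9 (-1.42 ± 0.18), with adjusted p between 2.16e-05 and 0.000122. The 8 largest decreases that the naming rule admits were headed by Scn4b, a sodium channel beta subunit (1.96 ± 0.445 to 0.197 ± 0.166 nRPKM; -3.24 ± 0.34, adjusted p = 2.29e-05). Next came the phosphatase inhibitor gene Ppp1r1c (-2.90 ± 0.45), the homeobox gene Irx4 (-2.52 ± 0.31), the serotonin receptor gene Htr1b (-2.22 ± 0.39) and Pvalb, encoding the calcium buffer parvalbumin (13.1 ± 0.163 to 2.87 ± 1.21 nRPKM; -2.17 ± 0.20). They were followed by Itpka (-2.11 ± 0.33), Hapln1 (-2.08 ± 0.29) and Trarg1 (-2.02 ± 0.23). Among markers of other neurons, the phosducin gene Pdc, a rod marker, fell (-0.64 ± 0.16, adjusted p = 0.0369; 1 of 14 rod markers, list adjusted p = 0.0794). The cone transducin gene Gnb3 rose (0.58 ± 0.08, adjusted p = 0.000248; 1 of 11 cone markers, list adjusted p = 0.542). The call of Pdc was lost without crushed vehicle replicate 1 or uncrushed vehicle replicate 1 or 3 (adjusted p up to 0.166). No bipolar, amacrine or horizontal cell marker passed (14, 12 and 6 measured; list adjusted p = 0.806, 0.236 and 0.573).

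Glial and immune genes rose. Of 22 reactive gliosis genes 15 rose (19 adjusted over the list alone; camera adjusted p = 5.19e-49, adjusted p = 0.00228 with an estimated correlation). They include the transcription factor gene Stat3 (14.1 ± 1.11 to 30.7 ± 2.81 nRPKM; log2 change 1.12 ± 0.11, edgeR quasi-likelihood adjusted p = 7.74e-06) and the growth factor gene Fgf2 (1.76 ± 0.23). Edn2, an endothelin released by stressed photoreceptors, rose from 7.87 ± 2.02 to 38.1 ± 7.76 nRPKM (2.28 ± 0.30). Of 20 microglia markers 8 rose (15 adjusted over the list alone; camera adjusted p = 2.32e-18, adjusted p = 0.0666 with an estimated correlation). Examples are the lysosomal gene Cd68 (1.64 ± 0.30), C1qb (1.09 ± 0.24), Laptm5 (0.79 ± 0.18) and Ptprc (1.12 ± 0.26). Of 21 interferon-stimulated genes 8 rose (20 adjusted over the list alone; camera adjusted p = 1.1e-23, adjusted p = 0.0585 with an estimated correlation), such as Gbp2 (1.91 ± 0.28), Bst2 (1.64 ± 0.38) and Gbp3 (1.62 ± 0.41). Of 13 complement, chemokine and cytokine genes 4 rose (8 adjusted over the list alone; camera adjusted p = 5.29e-11), among them Ccl2 (3.55 ± 0.72), Ccl5 (2.38 ± 0.54) and C4b (1.48 ± 0.34). Leaving out 1 vehicle library (for Gbp3 also 1 uncrushed DLKi library) ended the calls of C1qb, Laptm5, Ptprc, Bst2, Gbp3, Ccl2, Ccl5 and C4b, with adjusted p up to 0.0816, 0.107, 0.114, 0.113, 0.173, 0.0593, 0.124 and 0.0801. In each case the libraries included crushed vehicle replicate 1 and uncrushed vehicle replicate 2 or 3.

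In all, 510 of 19391 tested genes passed in vehicle retina (343 higher, 167 lower; 216 by at least 2-fold). Of the lens genes, which retinal tissue should hold at low levels, 0 of 16 measured passed, and 16 of 16 changes were negative (Mip -3.50 ± 1.15, adjusted p = 0.158, and Crybb2 -4.09 ± 1.61, adjusted p = 0.299, edgeR quasi-likelihood). The list's camera adjusted p of 0.000155 became adjusted p = 0.654 with an estimated correlation and 0.4 without uncrushed vehicle replicate 2. Lens scores were 0.805, 3.26 and -1.94 in the uncrushed and -2.18, -1.36 and 0.495 in the crushed vehicle libraries, so they did not follow the crush in each library. Cholesterol synthesis genes were lower (0 of 21; Insig1 -0.37 ± 0.10, gene adjusted p = 0.0683; list 0.00256, adjusted p = 0.69 with an estimated correlation). So were nuclear oxidative phosphorylation genes (0 of 28; list 0.00132, adjusted p = 0.69 with an estimated correlation). Glucocorticoid-responsive genes were higher (2 of 9, and 3 higher and 1 lower adjusted over the list alone; Mt2 1.08 ± 0.27, gene adjusted p = 0.038; list 0.0033, adjusted p = 0.181 with an estimated correlation). No gene passed in the lists of IRE1-XBP1 targets, ATF6 targets, DLK-JNK pathway components, Müller glia, infiltrating leukocyte, endothelial, pigment epithelium, skeletal muscle, oligodendrocyte, erythroid, drug-response or clock genes, whose adjusted p lay between 0.101 and 0.862. The count of 510 fell to 276, 279 and 318 without crushed vehicle replicate 1, uncrushed vehicle replicate 2 or uncrushed vehicle replicate 3. It was 281 (80.8% higher against 67.3%) when only the vehicle groups were fitted and 263 without the 3 libraries richest in lens transcripts. Without uncrushed vehicle replicate 1 it was 506, of which 248 were higher and 258 lower (49% higher), and without the pair of shallowest vehicle libraries 53.5% of the calls were higher. Single libraries also ended the calls of the cholesterol (crushed vehicle replicate 3, uncrushed 2 and 3; up to 0.239), glucocorticoid (crushed vehicle replicate 2, uncrushed 2; 0.109) and oxidative phosphorylation lists (crushed vehicle replicate 1; 0.0894). Mt2 was lost without 6 libraries (crushed vehicle replicates 1, 2 and 3, uncrushed 2 and 3, and uncrushed DLKi 4; up to 0.21).

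The second comparison asked how the retina responded to crush in mice given the inhibitor, in 5 crushed against 5 uncrushed DLKi retinas. The injury genes rose here too. Sprr1a rose from 0.082 ± 0.056 to 12.9 ± 3.9 nRPKM (log2 change 7.22 ± 0.32, edgeR quasi-likelihood adjusted p = 1.85e-10). Ecel1 rose from 0.164 ± 0.031 to 10.7 ± 1.61 (6.02 ± 0.20), Mmp12 from 0.074 ± 0.024 to 3.72 ± 0.602 (5.66 ± 0.20) and Cxcl10 from 0.062 ± 0.049 to 1.57 ± 0.575 (4.66 ± 0.44). Of the injury list 14 of 25 rose (16 adjusted over the list alone; camera adjusted p = 4.68e-63, adjusted p = 0.000653 with an estimated correlation). Tnfrsf12a, a receptor of the tumour necrosis factor family, rose from 3.21 ± 0.295 to 13.9 ± 3.9 nRPKM (2.12 ± 0.15). Of the ATF4 targets 14 rose (23 adjusted over the list alone; camera adjusted p = 4.62e-19, adjusted p = 0.00972 with an estimated correlation). Among them were Atf3 (2.01 ± 0.16), Atf5 (0.66 ± 0.08) and the proline synthesis genes Pycr1 (0.98 ± 0.13) and Aldh18a1 (0.50 ± 0.08). Jun (1.31 ± 0.13), Fosb (0.90 ± 0.14) and Junb (0.76 ± 0.16) were 3 of 4 immediate early genes that rose (8 adjusted over the list alone; camera adjusted p = 2.2e-08, adjusted p = 0.0939 with an estimated correlation). Hrk (3.47 ± 0.12) was 1 of 3 pro-apoptotic genes that rose (7 adjusted over the list alone; 4.7e-09). Cdkn1a (1.21 ± 0.12) and Phlda3 (0.44 ± 0.12) were the 2 p53 targets that rose (2 adjusted over the list alone; 0.00207). Of the aminoacyl-tRNA synthetases 4 rose (10 adjusted over the list alone; camera adjusted p = 4.71e-05, adjusted p = 0.176 with an estimated correlation), by 0.22 to 0.26. Bag3 rose by 0.62 ± 0.12. Calls of Tars, Nars, Gars and Phlda3 were each lost in fits without single DLKi libraries, always including crushed DLKi replicate 1 (adjusted p up to 0.0767, 0.082, 0.096 and 0.105).

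Ganglion cell markers fell and immune genes rose in inhibitor-treated mice as well. Of the 19 ganglion cell markers 16 fell (17 adjusted over the list alone; camera adjusted p = 1.62e-45, adjusted p = 0.00972 with an estimated correlation). Rbpms2 fell from 11.9 ± 1.25 to 3.75 ± 0.33 nRPKM (log2 change -1.66 ± 0.13, edgeR quasi-likelihood adjusted p = 4.26e-07). Nefh fell from 36.0 ± 2.92 to 13.0 ± 1.25 (-1.47 ± 0.13), and Chrna6 (-1.36 ± 0.14) and the microtubule protein gene Tppp3 (-1.26 ± 0.13) fell with it. Gliosis genes rose (19 of 22, 20 adjusted over the list alone; camera adjusted p = 1.01e-59, adjusted p = 0.00231 with an estimated correlation; Stat3 1.16 ± 0.08, Osmr 1.53 ± 0.17). Microglia markers rose (17 of 20, 20 adjusted over the list alone; 1.59e-35; Laptm5 1.04 ± 0.14, Itgam 1.22 ± 0.17, Cd68 1.62 ± 0.23), as did interferon-stimulated genes (20 of 21, 21 adjusted over the list alone; 6.25e-45; Gbp2 2.18 ± 0.22, Rsad2 2.58 ± 0.35, Ifit1 2.71 ± 0.39). Complement and chemokine genes rose too (8 of 13, 11 adjusted over the list alone; 1.09e-16; Ccl12 4.98 ± 0.71, C4b 1.63 ± 0.27). Mapk9 and Mapk10, which encode the kinases JNK2 and JNK3 downstream of DLK, fell slightly (-0.26 ± 0.05 and -0.45 ± 0.10, adjusted p = 0.00567 and 0.0118). They were the 2 of 11 pathway genes that passed (list 0.0158, adjusted p = 0.182 with an estimated correlation; 0.0639 without crushed DLKi replicate 1). Gnb3 (0.41 ± 0.06) and the Müller glia gene Clu (0.52 ± 0.11) also rose, and the horizontal cell gene Calb1 fell (-0.37 ± 0.08). The metallothionein genes Mt1 (0.78 ± 0.17) and Mt2 (1.16 ± 0.21) were among 3 of 9 glucocorticoid-responsive genes that rose (3 higher and 1 lower adjusted over the list alone; list 0.0158, adjusted p = 0.245 with an estimated correlation). Oxidative phosphorylation genes were lower as a list (0 of 28 called; 0.0158, adjusted p = 0.741 with an estimated correlation; up to 0.225 without uncrushed DLKi replicate 1 or 3 or crushed DLKi replicate 4 or 5). Of 21 cholesterol synthesis genes 4 fell (6 adjusted over the list alone; list 5.76e-05, adjusted p = 0.38 with an estimated correlation). Among them were Insig1 (-0.42 ± 0.08) and Nsdhl (-0.32 ± 0.08). Nsdhl was lost without crushed DLKi replicate 1 and other single DLKi libraries (adjusted p up to 0.0958).

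In all, 1034 genes passed with the inhibitor (638 higher, 396 lower; 334 by at least 2-fold), against 510 with vehicle in fewer retinas. Genes of neighbouring tissues differed between crushed and uncrushed DLKi retina, but not in each library. The lens score was 0.566 in uncrushed DLKi replicate 1 and 1.04 in crushed DLKi replicate 5. Of 16 lens genes 9 fell (16 adjusted over the list alone; camera adjusted p = 1.16e-08, adjusted p = 0.245 with an estimated correlation). Cryaa, an alpha crystallin, stood at 92.0 ± 101 nRPKM in uncrushed and 4.00 ± 2.73 in crushed DLKi retina (log2 change -4.52 ± 1.24, edgeR quasi-likelihood adjusted p = 0.0401). Cryba2 (-4.18 ± 1.07), Cryba1 (-4.08 ± 1.12), Crybb2 (-4.00 ± 1.11) and Cryba4 (-3.31 ± 0.91) also fell. All 5 lost their call without uncrushed DLKi replicate 3 or 5, among other DLKi libraries (adjusted p up to 0.113, 0.075, 0.12, 0.116 and 0.157). Krt5, a keratin of surface epithelium, was higher by 4.84 ± 1.10 (adjusted p = 0.0118), with 6.14 and 14.3 nRPKM in crushed DLKi replicates 3 and 5 and at most 0.532 in any other library. Calls of the vehicle and inhibitor responses overlapped in 269 higher and 144 lower genes, against 11.3 and 3.41 for independent lists. A share of 99.7% of the 343 genes raised with vehicle had a positive change with the inhibitor. The count of 1034 became 620 without the 3 libraries richest in lens transcripts. The share of higher genes was 51.3% in place of 61.7% when only the DLKi groups were fitted, and 52.8% (651 lower in place of 396) without the pair of shallowest vehicle libraries.

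**Figure D2:**
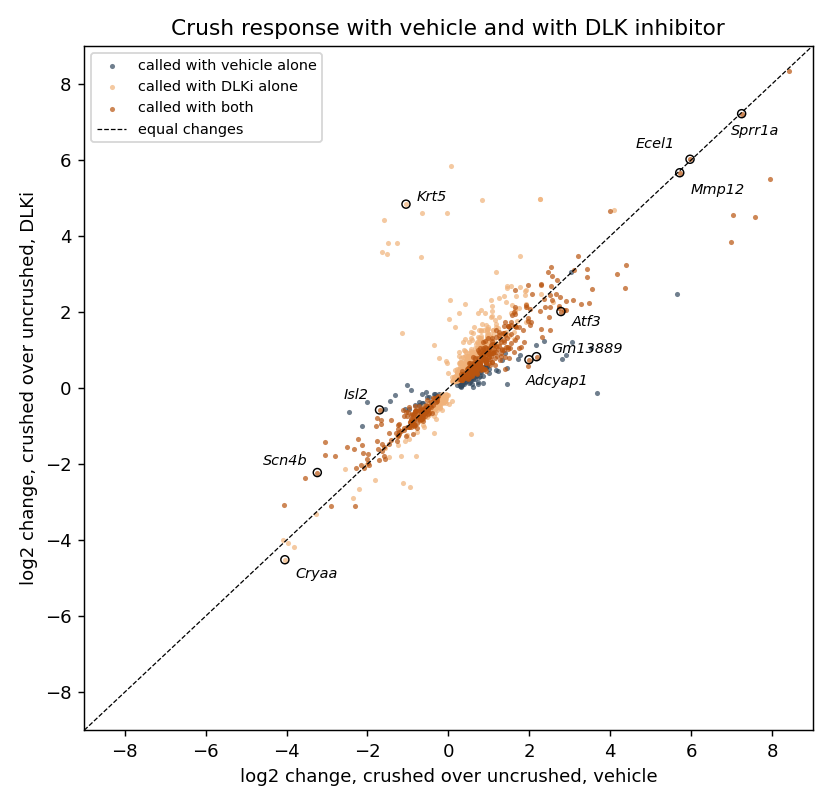
Log2 crush change per gene with vehicle (horizontal axis, 3 against 3 retinas) against that with DLKi (vertical axis, 5 against 5), for genes called in either comparison. With both treatments 413 genes were called, with vehicle alone 97 and with DLKi alone 621.

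The third comparison asked what the inhibitor changed in injured retina, in 5 crushed DLKi against 3 crushed vehicle retinas. Several injury genes were lower with the inhibitor. Atf3 stood at 8.99 ± 2.69 against 21.6 ± 1.53 nRPKM (SD; log2 change -1.26 ± 0.17, edgeR quasi-likelihood adjusted p = 0.00226) and Adcyap1, the neuropeptide PACAP induced by axotomy, at 1.37 ± 0.214 against 2.68 ± 0.28 (-0.97 ± 0.13, adjusted p = 0.00226). Tnfrsf12a stood at 13.9 ± 3.9 against 24.5 ± 2.19 (-0.81 ± 0.16, adjusted p = 0.0277). Stmn4, a tubulin-binding stathmin of neurons, stood at 16.9 ± 3.01 against 28.5 ± 6 (-0.76 ± 0.15, adjusted p = 0.0287) and Sprr1a at 12.9 ± 3.9 against 24.9 ± 4.25 (-0.95 ± 0.20, adjusted p = 0.0435). Of the 25 injury genes 5 were lower and 0 higher (8 adjusted over the list alone; camera adjusted p = 2.68e-08, adjusted p = 0.297 with an estimated correlation). Among death and stress genes, Bcl2l11, encoding BIM, stood at 2.56 ± 0.315 against 3.65 ± 0.253 (-0.51 ± 0.10, adjusted p = 0.0333) and Cdkn1a at 5.17 ± 0.586 against 8.24 ± 0.554 (-0.67 ± 0.13, adjusted p = 0.0287). In all 2 of 19 pro-apoptotic genes were lower (3 adjusted over the list alone; 0.000404, adjusted p = 0.227 with an estimated correlation). The calls of Atf3 and Adcyap1 held in each of 16 fits leaving out 1 library. The other 5 were each lost without crushed vehicle replicates 1, 2 or 3. Further libraries that ended a call were crushed DLKi 4 or 5 for Tnfrsf12a (up to 0.182), 1 or 5 for Stmn4 (0.128) and 1, 3, 4 or 5 for Cdkn1a (0.134). For Bcl2l11 they were crushed DLKi 1, 2, 3 or 5 and uncrushed DLKi 4 (0.187), and Sprr1a was lost without 12 libraries (0.207).

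Of the ganglion cell markers, 3 transcription factor genes were higher with the inhibitor in crushed retina. The POU-domain factor gene Pou4f1, encoding BRN3A (Entrez 18996, GRCm38 chromosome 14, 104461675 to 104468118), stood at 6.11 ± 1.11 against 2.31 ± 0.916 nRPKM (log2 change 1.39 ± 0.23, edgeR quasi-likelihood adjusted p = 0.0108). It stood at 6.34 ± 1.68 in uncrushed vehicle and 7.68 ± 0.935 in uncrushed DLKi retina. Isl2 (Entrez 104360, GRCm38 chromosome 9, 55538677 to 55547667) stood at 1.40 ± 0.076 against 0.535 ± 0.179 (1.37 ± 0.19, adjusted p = 0.0032) and Pou4f2, encoding BRN3B, at 2.58 ± 0.442 against 0.982 ± 0.608 (1.37 ± 0.27, adjusted p = 0.0277). Rbpms2, at 3.75 ± 0.33 against 3.12 ± 0.902 nRPKM, and Nefh, at 13.0 ± 1.25 against 10.1 ± 3.3, did not pass. Of 19 markers 3 were higher (5 adjusted over the list alone) and 19 of 19 changes were positive (camera adjusted p = 5.04e-11, adjusted p = 0.536 with an estimated correlation). The list's score was higher with the inhibitor in both crushed (5.14 against 4.671) and uncrushed retina (5.959 against 5.624). The difference of crush effects was positive in 7 markers and negative in 12. Outside the lists, Scn4b (1.59 ± 0.33, adjusted p = 0.0349), the scaffold gene Ahnak2 (1.06 ± 0.19, adjusted p = 0.0172), the mitochondrial adenylate kinase gene Ak4 (0.63 ± 0.12, adjusted p = 0.0187) and the exonuclease gene Exo5 (0.55 ± 0.11, adjusted p = 0.026) were higher. The complement factor I gene Cfi was the 1 of 13 complement, chemokine and cytokine genes that was higher (0.96 ± 0.20, adjusted p = 0.0393; 1 adjusted over the list alone; list 0.453). The call of Isl2 held in each of 16 fits leaving out 1 library, and that of Pou4f1 was lost without crushed vehicle replicate 1 (adjusted p = 0.0565). Those of Ahnak2 and Ak4 were lost without crushed vehicle 1 or 3 (up to 0.149 and 0.163). The same 2 libraries ended the other calls, with crushed DLKi 2, 3 or 5 for Pou4f2 (0.188) and crushed vehicle 2 and crushed DLKi 1, 2, 3 or 5 for Exo5 (0.13). Scn4b was lost without 9 libraries (0.187) and Cfi without 10 (0.183).

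**Figure D3:**
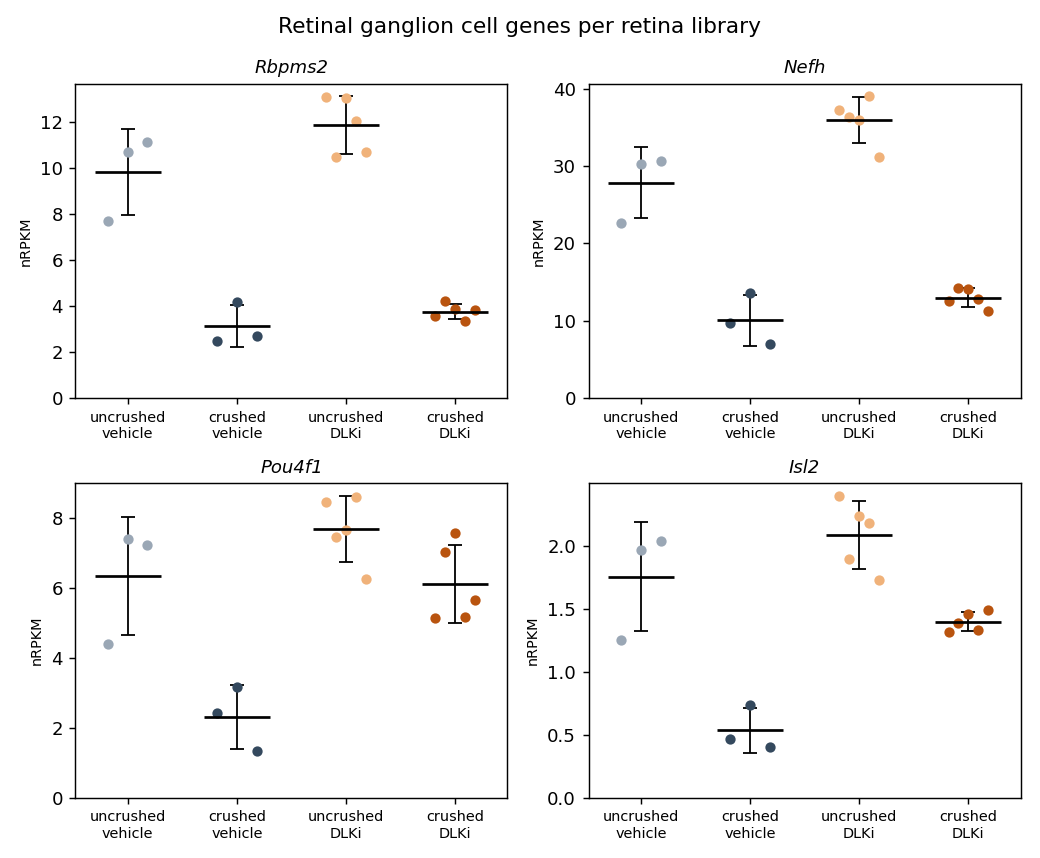
Rbpms2, Nefh, Pou4f1 and Isl2, 4 genes of retinal ganglion cells, as deposited nRPKM per library in the 4 groups (points are libraries, bars mean ± SD; n = 3 per vehicle and 5 per DLKi group). Pou4f1 spans 1.348 to 3.171 in crushed vehicle and 5.149 to 7.563 in crushed DLKi retina, while the Rbpms2 ranges, 2.486 to 4.149 and 3.324 to 4.199, overlap.

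In all, 98 genes passed in crushed retina (25 higher, 73 lower; 14 by at least 2-fold; 2665 at an unadjusted p under 0.05). Besides that of Atf3, the largest decreases that the naming rule admits (a mean of at least 1 CPM and a proper symbol) were those of Rspo2, a secreted activator of Wnt signalling (0.109 ± 0.018 against 0.321 ± 0.041 nRPKM; log2 change -1.55 ± 0.24, edgeR quasi-likelihood adjusted p = 0.0084), and Tcp11, a testis-expressed gene (3.33 ± 0.763 against 8.76 ± 0.898; -1.39 ± 0.15, adjusted p = 0.000576). Alkal2, a ligand of the ALK receptor (-1.24 ± 0.24, adjusted p = 0.0284), and Ncmap, a myelin-associated protein (-0.90 ± 0.17, adjusted p = 0.0242), were lower too. Jund was lower by 0.52 ± 0.11 on the log2 scale. Exons of Alkal2 and Jund overlap those of a gene on the other strand over 35.1% and 52.6% of their length, and the kit does not mark strand, so both are uncertain. Of the aminoacyl-tRNA synthetases Mars1 was higher (0.30 ± 0.06, adjusted p = 0.0365; 8 adjusted over the list alone; camera adjusted p = 7.18e-08, adjusted p = 0.263 with an estimated correlation). The lists of bipolar cell markers (0 called, 2 adjusted over the list alone; Cabp5 0.30 ± 0.08, gene adjusted p = 0.0845; list 0.00209) and oxidative phosphorylation genes (0 called, 28 of 28 positive; Sdha 0.22 ± 0.06, gene adjusted p = 0.147; list 2.89e-06) were higher, both with adjusted p = 0.861 with an estimated correlation. Those of cholesterol synthesis (0 called; Dhcr7 -0.31 ± 0.08, gene adjusted p = 0.117; list 0.00117) and gliosis genes (0 called; Socs3 -0.42 ± 0.20, gene adjusted p = 0.377; list 0.0435) were lower, again with adjusted p = 0.861 with an estimated correlation. The cholesterol list lost its call without crushed vehicle replicate 2 (0.108). The gliosis list lost it without crushed vehicle replicate 1 or 2, crushed DLKi 3, 4 or 5, or uncrushed DLKi 5 (up to 0.338). The lists of ATF4 targets (adjusted p = 0.453; Atf3 the 1 member called), microglia markers (0.933) and interferon-stimulated genes (0.249) did not pass. The count of 98 was 22, 36 and 25 without crushed vehicle replicates 1, 2 and 3, and 59, 56, 50 and 52 without crushed DLKi replicates 1, 2, 3 and 5. It was 45 when only the crushed groups were fitted, and 420, of which 43.1% were higher against 25.5%, with DESeq2. Over fits leaving out 1 library 13.6% to 41.7% of the calls were higher, the extremes being without crushed vehicle replicates 1 and 2. Tcp11 held throughout and Rspo2 lost its call without crushed vehicle replicate 1 (0.0553). Alkal2, Ncmap, Jund and Mars1 lost theirs without crushed vehicle replicates 1 or 3 among others (up to 0.183, 0.132, 0.123 and 0.174).

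The genes raised by crush and those lowered by the inhibitor in crushed retina shared 15 members, against 1.29 for independent lists. They were Adcyap1, Alkal2, Atf3, Bcl2l11, Cdkn1a, Dusp8, Fam214b, Fcamr, Gm13889, Mlf1, Sprr1a, Sprr2g, Stmn4, Tnfrsf12a and Ttyh2. For Stmn4 (log2 change 1.40 with vehicle and 1.73 with the inhibitor) and Fcamr (0.64 and 0.68) the crush rise was no smaller with the inhibitor. For the others it was smaller, for Sprr1a only from 7.25 to 7.22. Only Adcyap1 and Gm13889 of the 15 passed the test of the difference of crush effects. Stmn4, Fcamr and Mlf1 were also called lower with the inhibitor in uncrushed retina. Genes lowered by crush and raised by the inhibitor numbered 7, against 0.215. Both contrasts use the same 3 crushed vehicle libraries, which pulls them in opposite directions by chance. A set of 20 simulations with no effect gave a correlation over genes of -0.623 to -0.484 (observed -0.271) and a covariance of -0.0204 to -0.0141 (observed -0.0177). They gave 0 shared calls in either direction, but they hold no genes with a real change, so this 0 does not measure what sharing adds among genes that respond. The contrasts were not fitted with separate crushed vehicle libraries, so part of the excess over the independent number may come from the sharing.

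The fourth comparison asked what the inhibitor changed in the uninjured eye, in 5 uncrushed DLKi against 3 uncrushed vehicle retinas. With 5 mice stated per drug, these DLKi retinas would be the other eyes of crushed mice, so the comparison holds no uninjured inhibitor-treated animal. Several ATF4 target and aminoacyl-tRNA synthetase genes were higher. Chac1 (Entrez 69065, GRCm38 chromosome 2, 119351242 to 119354326) stood at 4.93 ± 1.21 against 2.34 ± 0.223 nRPKM (SD; log2 change 1.07 ± 0.18, edgeR quasi-likelihood adjusted p = 0.0145). Mthfd2, a mitochondrial folate enzyme, stood at 7.06 ± 0.967 against 4.12 ± 0.311 (0.77 ± 0.11, adjusted p = 0.00535) and Aldh18a1 at 12.2 ± 0.611 against 8.50 ± 0.532 (0.52 ± 0.09, adjusted p = 0.0159). The cationic amino acid transporter gene Slc7a1 stood at 4.98 ± 0.404 against 3.53 ± 0.301 (0.49 ± 0.10, adjusted p = 0.0332). Of 20 aminoacyl-tRNA synthetases 9 were higher (16 adjusted over the list alone; camera adjusted p = 2.33e-18). Yars stood at 37.3 ± 3.53 against 25.2 ± 2.96 nRPKM (0.56 ± 0.09, adjusted p = 0.0113), and the changes of Iars, Gars and Nars were 0.33 ± 0.06, 0.42 ± 0.08 and 0.43 ± 0.08. Of 32 ATF4 targets 4 were higher (17 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.52e-11, adjusted p = 0.13 with an estimated correlation). Ak4 was higher (0.56 ± 0.11, adjusted p = 0.0344). The call of Mthfd2 held in each of 16 fits leaving out 1 library. That of Yars was lost without uncrushed vehicle replicate 1 (adjusted p = 0.0684), and that of Chac1 without uncrushed vehicle 1 or 2 (0.0814). Those of Gars, Nars, Iars, Aldh18a1, Slc7a1 and Ak4 were lost without uncrushed vehicle 1 or 2 or uncrushed DLKi 3 or 4, among others for the last 4 (up to 0.125, 0.125, 0.0814, 0.0839, 0.153 and 0.187).

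**Figure D4:**
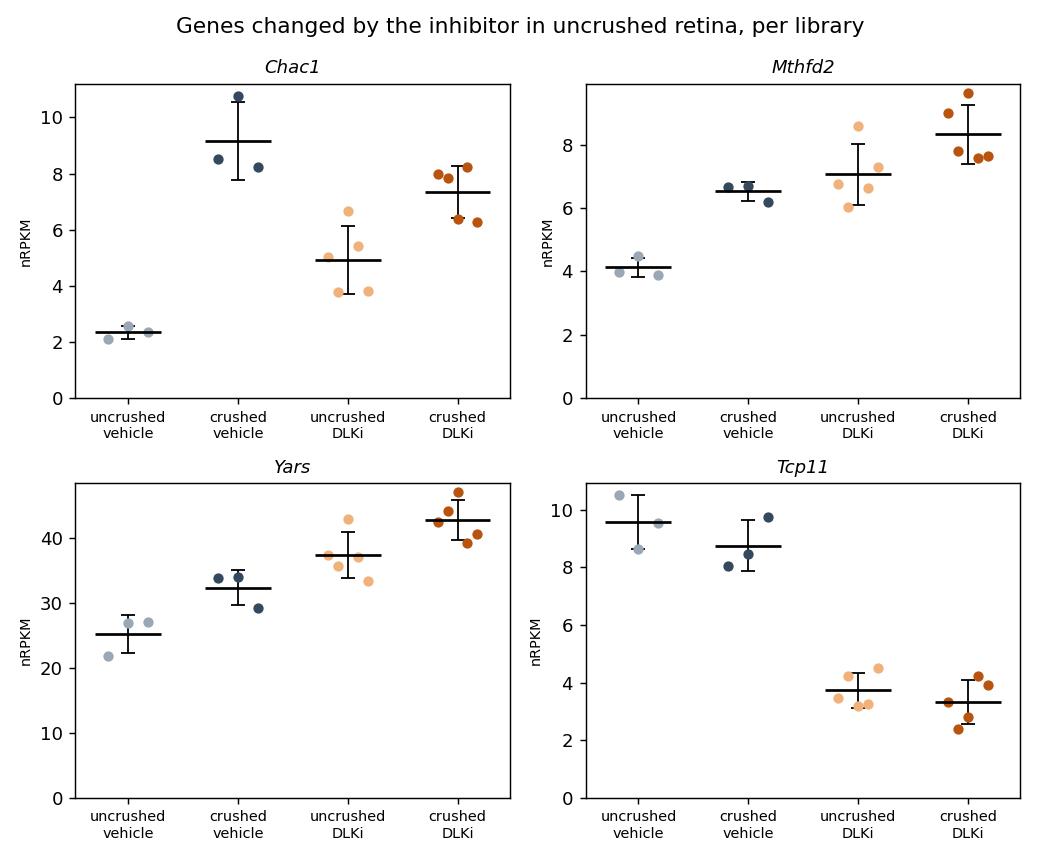
Chac1, Mthfd2, Yars and Tcp11 as deposited nRPKM per library in the 4 groups (points are libraries, bars mean ± SD; n = 3 per vehicle and 5 per DLKi group). Mthfd2 spans 3.9 to 4.477 in uncrushed vehicle and 6.045 to 8.6 in uncrushed DLKi retina, and Tcp11 spans 8.042 to 10.51 over the 6 vehicle and 2.393 to 4.517 over the 10 DLKi libraries.

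Other genes were lower with the inhibitor in uncrushed retina. Tcp11 stood at 3.73 ± 0.605 against 9.57 ± 0.929 nRPKM (log2 change -1.36 ± 0.15, edgeR quasi-likelihood adjusted p = 0.000734) and Rspo2 at 0.141 ± 0.046 against 0.451 ± 0.094 (-1.67 ± 0.22, adjusted p = 0.00393). Stmn4 stood at 5.11 ± 0.353 against 10.8 ± 2.23 (-1.09 ± 0.16, adjusted p = 0.00535) and Jun at 6.84 ± 0.987 against 11.0 ± 1.9 (-0.69 ± 0.15, adjusted p = 0.0402). Of 19 pro-apoptotic genes 1 was lower (5 adjusted over the list alone; list 0.0105, adjusted p = 0.378 with an estimated correlation). The meiotic genes Fbxo43 (0.141 ± 0.039 against 0.286 ± 0.041 nRPKM, adjusted p = 0.0451) and Tex15 (-0.96 ± 0.20, adjusted p = 0.0347), the p53 target Trp53inp1 (-0.41 ± 0.07, adjusted p = 0.0158) and the glucocorticoid-responsive kinase gene Sgk1 (-0.37 ± 0.07, adjusted p = 0.0332) were also lower. Tcp11, Rspo2 and Stmn4 held in each of 16 fits leaving out 1 library. Trp53inp1 lost its call without uncrushed vehicle replicates 1, 2 or 3 or uncrushed DLKi 3 or 4 (adjusted p up to 0.0815). Tex15, Sgk1, Jun and Fbxo43 lost theirs without 7, 7, 9 and 14 libraries (0.157, 0.193, 0.17 and 0.213), uncrushed vehicle 1 and 2 and uncrushed DLKi 1, 3 and 4 among them.

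In all, 122 genes passed in uncrushed retina (51 higher, 71 lower; 7 by at least 2-fold; 3349 at an unadjusted p under 0.05). Ganglion cell (0 called; Thy1 0.43 ± 0.16, gene adjusted p = 0.188; list 2.16e-06), oxidative phosphorylation (0 called; Sdha 0.25 ± 0.06, gene adjusted p = 0.0943; list 0.00208), heat shock (0.0144) and amacrine cell genes (0.00578) were higher as lists. Cholesterol synthesis (0.0144), microglia (0.0121), gliosis (0.0224) and pigment epithelium genes (0.00698) were lower. Each of these 8 lists had adjusted p = 0.782 with an estimated correlation. Bipolar cell markers (list 0.000138) were higher with adjusted p = 0.714 with an estimated correlation. Lens genes were higher as a list (0 called; 0.00345, adjusted p = 0.782 with an estimated correlation). Their summed nRPKM was highest, at 288.8, 389.2 and 703.7, in uncrushed vehicle replicate 2 and uncrushed DLKi replicates 3 and 5. Of these lists only the ganglion cell, bipolar cell and oxidative phosphorylation ones kept their call in each fit leaving out 1 library. Those of amacrine (0.999) and heat shock genes (0.0623) were lost without uncrushed vehicle replicate 1, those of pro-apoptotic genes without uncrushed vehicle 3 (0.0885), and lens genes without uncrushed DLKi 5 or uncrushed vehicle 3 (up to 0.391). Those of pigment epithelium (0.799), microglia (0.0872), cholesterol (0.419) and gliosis genes (0.312) were lost without uncrushed DLKi 5 or 2, among others. The count of 122 was 19, 17 and 63 without uncrushed vehicle replicates 1, 2 and 3, 57, 23, 26 and 205 without uncrushed DLKi replicates 1, 3, 4 and 5, and 70 without crushed DLKi replicate 1. Only 3 genes passed when only the uncrushed groups were fitted, 7 without the 3 libraries richest in lens transcripts and 11 without the pair of shallowest vehicle libraries. DESeq2 called 625 (54.6% higher against 41.8%). Over fits leaving out 1 library 17.6% to 45.2% of the calls were higher, the extremes being without uncrushed vehicle replicate 2 and crushed vehicle replicate 3.

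Both inhibitor comparisons called the same 9 genes higher and the same 39 lower, against 0.0658 and 0.267 for independent lists. The comparisons share no library. With 5 mice stated per drug, however, the 5 crushed and 5 uncrushed DLKi retinas would come from the same mice. The comparisons would then share animals. The numbers for independent lists leave this sharing out, so part of the excess over them may come from it. The labels do not say which crushed and uncrushed retinas came from the same mouse. Besides Tcp11, Rspo2 and Stmn4 the lower ones included Abca1, a cholesterol exporter (log2 change -0.74 ± 0.08 in crushed and -0.92 ± 0.09 in uncrushed retina, edgeR quasi-likelihood adjusted p = 0.00068 and 7.39e-05). Another was Cdk19, a kinase of the Mediator complex (-0.71 and -0.72, adjusted p = 0.00226 and 0.00393). Both lie outside the naming rule and were chosen after their values were seen. Ak4 and Mars1 were among the 9 higher ones.

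The last comparison asked whether the crush response itself differed between inhibitor and vehicle. In this test of the difference 2 of 19391 genes passed (edgeR quasi-likelihood; 298 at an unadjusted p under 0.05; 5 with DESeq2 and 1 with limma-voom), both with a smaller rise under the inhibitor. Gm13889, a gene model without a proper symbol that was chosen after its values were seen (Entrez 620695), went from 14.1 ± 3.36 to 64.3 ± 5.3 nRPKM with vehicle and from 17.8 ± 1.17 to 31.5 ± 3.26 with the inhibitor (difference of log2 changes -1.35 ± 0.17, adjusted p = 0.00551). Adcyap1 went from 0.666 ± 0.142 to 2.68 ± 0.28 and from 0.819 ± 0.044 to 1.37 ± 0.214 (-1.24 ± 0.19, adjusted p = 0.0454). The next named genes, Chac1 (-1.39 ± 0.24, adjusted p = 0.139), Isl2 (1.13 ± 0.25), Pou4f1 (1.12 ± 0.30), Cdkn1a (-0.66 ± 0.20) and the folate enzyme gene Aldh1l2 (-0.63 ± 0.17; adjusted p = 1 for the last 4), did not pass in this test, which pairs no retinas. As lists, ATF4 targets (camera adjusted p = 1.07e-15, adjusted p = 0.0892 with an estimated correlation), aminoacyl-tRNA synthetases (6.62e-06, adjusted p = 0.51 with an estimated correlation), immediate early genes (0.00173) and axon injury genes (0.000101) rose less with the inhibitor. Microglia markers (0.000923) and interferon-stimulated genes (3.01e-05) rose more. The last 4 lists had adjusted p = 0.925 with an estimated correlation. The ATF4 score, a mean log2 value over the list, was 4.19 ± 0.0519 and 4.81 ± 0.0734 in uncrushed and crushed vehicle and 4.44 ± 0.0848 and 4.82 ± 0.0805 in uncrushed and crushed DLKi retina. In the same order the microglia score was 1.89 ± 0.031, 2.70 ± 0.111, 1.66 ± 0.243 and 2.67 ± 0.395. The interferon score was 1.16 ± 0.121, 2.56 ± 0.38, 0.934 ± 0.161 and 2.74 ± 0.729. The larger rise of the microglia list thus came from a lower score in uncrushed DLKi retina, not from a higher one after crush. Adcyap1 kept its call in 2 of 16 fits leaving out 1 library, those without crushed DLKi replicate 2 or uncrushed vehicle replicate 2 (adjusted p up to 0.263 in the others, where 1 gene passed), and Gm13889 in all 16. The immediate early list was lost without crushed vehicle 1, uncrushed vehicle 1 or uncrushed DLKi 2 (up to 0.425). The interferon list was lost without crushed DLKi 4 or crushed vehicle 3 (0.393) and the microglia list without crushed DLKi 1 or 2 or crushed vehicle 3 (0.174).

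**Figure D5:**
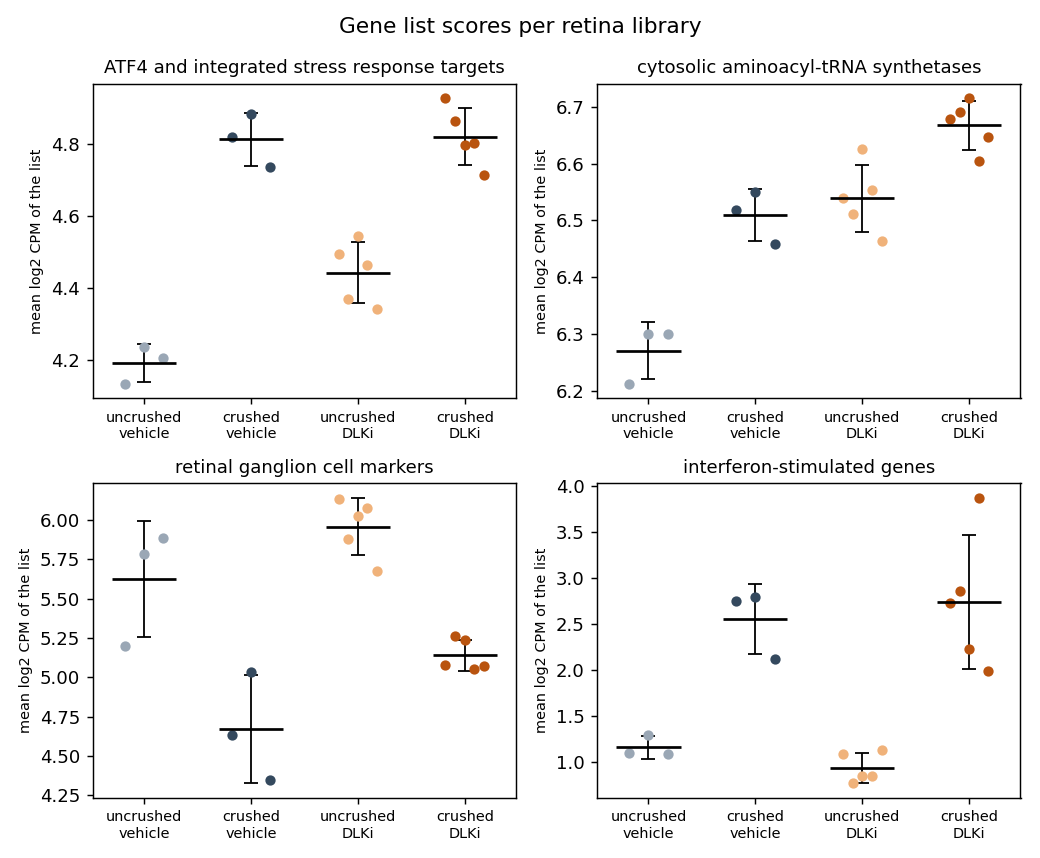
Scores of ATF4 targets, aminoacyl-tRNA synthetases, ganglion cell markers and interferon-stimulated genes per library, each the mean log2 value over the list's measured genes (points are libraries, bars mean ± SD; n = 3 per vehicle and 5 per DLKi group). The mean ATF4 score is 4.19 in uncrushed vehicle, 4.813 in crushed vehicle, 4.442 in uncrushed DLKi and 4.821 in crushed DLKi retina.

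The size of the crush response with and without the inhibitor was then compared over all responding genes. The average of both crush effects called 1639 genes (1012 higher, 627 lower), such as Sprr1a and Rbpms2, and their median log2 change in the called direction was 0.5278 with vehicle and 0.4896 with the inhibitor. The ratio of these medians, 0.9278, lay within the 0.8686 to 0.9386 found in 50 simulations with equal effects in both groups. The change was smaller with the inhibitor in 53.75% of the genes, below the simulated 55.11% to 61.1%. The simulations called 2287 to 2447 genes, more than the real data, so they do not match the retinas in every respect. Among genes raised by crush the share was 57.51%, within the simulated 54.34% to 60.49%, and among genes lowered it was 47.69%, below the simulated 55.14% to 61.77%. That last share was 74.34% without crushed vehicle replicate 2 and 75.18% without uncrushed vehicle replicate 1, both above the simulated range. Over fits leaving out 1 library the share of all genes moved between 47.49%, without crushed DLKi replicate 3, and 65.57%, without crushed vehicle replicate 2.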

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

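All tests of explanations and of other splits of the samples in this part were chosen only after the results they bear on were seen.

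The test of the difference between the crush responses picked out 2 genes and 6 lists. Adcyap1 (-1.24 on the log2 scale) and Gm13889 (-1.35) rose less after crush with the inhibitor, by the edgeR quasi-likelihood test. ATF4 targets (camera adjusted p = 1.07e-15), aminoacyl-tRNA synthetases (6.62e-06), immediate early genes (0.00173) and axon injury genes (0.000101) shifted the same way, and microglia markers (0.000923) and interferon-stimulated genes (3.01e-05) the other way. With an estimated correlation the smallest adjusted p of the 6 was 0.0892, for the ATF4 targets. Chance was not excluded for the count of 2 genes: 5 of 100 splits of the samples called as many, and the highest of the others called 2417, which points to a structure of the samples other than the groups.

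The other counts of called genes were set against other splits of the same libraries. For the crush effect with vehicle the real value was 510 and the highest of the other 9 splits 166, but 10 splits are too few for a share under 0.05. For the crush effect with the inhibitor (1034) 1 of 100 splits, the real one, gave as many, and the highest other gave 301. In crushed retina (98) it was 1 of 56, with 17 for the highest other. Chance was excluded at 0.05 for the crush effect with the inhibitor and for the inhibitor effect in crushed retina. In uncrushed retina (122) 2 of 56 splits gave as many. The other called 212 genes by setting uncrushed vehicle replicate 1 and uncrushed DLKi replicates 3 and 5 apart from the remaining 5 libraries. That share was also under 0.05, but the libraries hold a structure that called more genes than the drug, so the count there is not clear of chance.

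Single libraries stood far from the other 4 of their group in 15 of 242 values tested (10 of 168 gene levels and 5 of 66 list scores among them), where chance gives about 1 in 20. In crushed DLKi replicate 2 Ptgfr stood at 0.962 nRPKM (others 0.286 to 0.44) and Pvalb at 4.61 (3.74 to 3.88). Rsad2 stood at 1.97 in crushed DLKi replicate 4 (0.458 to 0.802), Pou4f2 at 3.36 in replicate 3 (2.26 to 2.52) and Fbxo43 at 0.219 in replicate 5 (0.133 to 0.157). Uncrushed DLKi replicate 5 held 4 such values: Mapk10 at 11.8 nRPKM (13.3 to 13.5) and the scores of amacrine (5.43 against 5.6 to 5.66), horizontal (2.66 against 2.99 to 3.05) and skeletal muscle markers (1.6 against 1.2 to 1.27). Uncrushed DLKi replicate 2 held 3: Mmp12 at 0.0323 (0.0785 to 0.0952), Atf3 at 2.58 (2.08 to 2.22) and Ptgfr at 0.144 (0.0655 to 0.0814). Uncrushed DLKi replicate 3 had Gm13889 at 19.9 (16.9 to 17.7) and a bipolar cell score of 7.03 (6.87 to 6.9), and uncrushed DLKi replicate 1 a Müller glia score of 8.06 (7.77 to 7.83).

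The first pattern weighed was the higher level of aminoacyl-tRNA synthetase and ATF4 target genes in uncrushed DLKi retina, with median log2 changes of 0.277 and 0.253. With all libraries thinned to the shallowest the medians were 0.272 and 0.268. Thinning keeps the expected ratios between libraries, so it could not have lowered these medians and does not decide on depth. The medians were 0.237 and 0.239 without the pair of shallowest vehicle libraries. Without the 3 libraries richest in lens transcripts they were 0.294 and 0.213. These values argue against that pair or those libraries as the whole cause. The lists share 0 genes. An effect of the drug on the stress response behind these lists is a hypothesis that stays open. So do batches of housing or dosing, which the labels do not give and which may follow the drug. The library numbers do follow the drug: the DLKi libraries form an unbroken run, with vehicle libraries only before and after it. In both inhibitor comparisons an effect of library order was therefore not separated from that of the drug.

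The second pattern was the set of 48 genes that both inhibitor comparisons called with the same sign. After thinning, their median absolute change was 0.472 (0.467 before) and 37 were still called in both, so those calls did not need the extra depth. Thinning keeps the expected ratios between libraries, so it could not have lowered the changes themselves and does not decide on depth as their cause. When the 8 pairs of consecutive library numbers were split in every way into 3 and 5, 1 of 56 splits, the real one, shared as many genes and the highest other shared 0, so chance was excluded. An action of the inhibitor that needs no injury to the same eye is a candidate explanation, but a shared batch of dosing or an effect of library order was untested. With 5 mice stated per drug, the uncrushed DLKi retinas would be the other eyes of crushed mice. An action that needs no injury at all therefore cannot be told apart from one that follows injury of the other eye.

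The third pattern was lens genes lower and ocular surface genes higher after crush with the inhibitor. Lens genes varied together within groups with a median pairwise correlation of 0.844 and ocular surface genes with 0.812, but amacrine cell markers, which belong to the retina, did so at 0.87, so tissue carried over at dissection cannot be told apart from a change in the retina by this measure. Cryaa ran from 0.0211 to 232 nRPKM; 16 lens genes were measured, 1 also stands in another list, and 1 reached 1 nRPKM in crushed vehicle replicate 1, which had the lowest lens score. Only 5 of 8 uncrushed libraries had a lens score above the highest crushed one, which leaves a loss of lens transcripts after crush in the retina itself open as well. Uneven dissection is a candidate source of both, since Krt5 reached 6.14 and 14.3 nRPKM in 2 crushed DLKi libraries and at most 0.532 in the other 14.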

How the results depend on the processing

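Leaving out the pair of shallowest vehicle libraries, leaving out the 3 libraries richest in lens transcripts, and thinning were tests chosen only after the results were seen; the other alternatives were planned. Of the results for named genes, RLE size factors left 435 on their side of the threshold and ended 1, and limma-voom left 417 and ended 18. Calls ended numbered 68 without the lens-rich libraries, 43 without the shallowest vehicle pair, 42 with only the groups compared and 39 without crushed vehicle replicate 2 and uncrushed vehicle replicate 3. Of 165 list results these size factors changed 0 and the estimated correlation ended 40. The cause was not tested for the changes below. Genes called in the crush effect with vehicle (510) numbered 281 when only its groups were fitted, 258 without crushed vehicle replicate 2 and uncrushed vehicle replicate 3, 263 without the lens-rich libraries and 276 to 506 over fits leaving out 1 library; with the inhibitor (1034) 689 at a log2 change of at least 0.5, 620 without the lens-rich libraries and 748 to 1258. In crushed retina (98) the inhibitor effect gave 420 with DESeq2, 45 in its groups alone, 44 at 0.5, 38 without that vehicle pair, 53 without the shallowest pair and 22 to 144; in uncrushed retina (122) 625 with DESeq2, 3 in its groups alone, 39 at 0.5, 11 without the shallowest pair, 7 without the lens-rich libraries and 17 to 205. The difference of crush effects (2) gave 5 with DESeq2, 1 with limma-voom, without either vehicle pair and with thinned counts, 0 without the lens-rich libraries (edgeR, 328 at an unadjusted p under 0.05), and 1 to 2.

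Consecutive library numbers as a replicate block, which the labels do not call pairs, gave 1234 genes for the crush effect with vehicle, 2080 with the inhibitor, and 3 genes (850 at an unadjusted p under 0.05) and 10 lists for the difference (2 genes, 298 and 6 lists without it). The third gene was Pou4f1: difference of crush effects (DLKi minus vehicle), with an edgeR quasi-likelihood adjusted p = 0.0226, against 0.474 to 1 in the other alternatives. Isl2: difference of crush effects (DLKi minus vehicle) passed with DESeq2 (adjusted p = 0.03) and in no other alternative (0.0635 to 1). Deviations of the paired libraries correlated at 0.056 to 0.68, 7 of 8 pairs above 0.1, and 13 of 16 libraries were closest to their own partner, a hint from the data and not the design. With the estimated correlation 8 of 15 lists for the crush effect with vehicle, 9 of 16 with the inhibitor, 0 of 8 for the inhibitor effect in crushed retina, 1 of 13 in uncrushed retina and 0 of 6 for the difference passed; fry gave 2, 2 and 0 in the last 3. Without crushed vehicle replicate 2 and uncrushed vehicle replicate 3, 8 lists passed in uncrushed retina and 12 for the difference; over fits leaving out 1 library the lists numbered 8 to 14 and 5 to 13. Without uncrushed vehicle replicate 1, 2 lists that had not passed did so in the opposite direction. These were amacrine cell markers: difference of crush effects (DLKi minus vehicle) at 0.0194 (6.39e-05 to 0.855 over fits leaving out 1 library) and cholesterol biosynthesis genes: difference of crush effects (DLKi minus vehicle) at 0.0245 (0.019 to 0.989). The share of crush-response genes smaller with the inhibitor (53.75%) was 72.75% over the 510 genes called with vehicle, 34.62% over the 1034 called with the inhibitor, 60.54% without that vehicle pair, 56.94% without the shallowest pair, 52.27% without the lens-rich libraries and 47.49% to 65.57% over fits leaving out 1 library. Thinned to the shallowest library, the inhibitor comparisons called 87 and 104 genes.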

Other observations

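The 6 gene lists of the first 2 paragraphs and all tests in the last paragraph were chosen only after the results were seen.

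Crush raised genes of dividing cells and of antigen presentation, and lowered ion channel genes, with either treatment. Of 23 cell cycle genes 4 rose with vehicle (6 adjusted over the list alone; camera adjusted p = 7.25e-07, adjusted p = 0.0513 with an estimated correlation) and 7 with the inhibitor (13; 3.37e-10), among them Top2a, the topoisomerase of dividing cells (log2 change 2.68 ± 0.46 and 2.83 ± 0.37; edgeR quasi-likelihood adjusted p = 0.00238 and 0.000124), and Mki67 (2.47, lost without crushed vehicle replicate 1 or uncrushed vehicle replicate 2 or 3 at up to 0.165, and 3.06 ± 0.48). Of 18 MHC class I genes 4 rose with vehicle (13 adjusted over the list alone; 2.88e-14, adjusted p = 0.0739 with an estimated correlation) and 12 with the inhibitor (15; 1.35e-21), with Nlrc5, the regulator of the class, at 2.46 ± 0.29, H2-Q4 at 1.47 ± 0.19 and B2m, the common light chain, at 1.00 ± 0.18 under the inhibitor; counts of H2 genes are uncertain because near-identical copies share reads. Of 27 voltage-gated sodium and potassium channel genes 7 fell with vehicle (12 adjusted over the list alone; 7.46e-16, adjusted p = 0.0744 with an estimated correlation) and 14 with the inhibitor (18; 2.23e-22), including Kcnd2 (-1.23 ± 0.20), Scn1a (-0.93 ± 0.18) and the channel partner Kcnip4 (-0.92 ± 0.15) with vehicle.

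In uncrushed retina the inhibitor went with higher ribosome biogenesis genes, 5 of 24 (7 adjusted over the list alone; camera adjusted p = 1.09e-05, adjusted p = 0.0915 with an estimated correlation), such as Nop2, a ribosomal RNA methyltransferase (log2 change 0.33 ± 0.06, edgeR quasi-likelihood adjusted p = 0.0258), and Utp14a (0.35, adjusted p = 0.0277), and with lower FOXO-associated genes, 4 of 20 (4 adjusted over the list alone; 0.00198, adjusted p = 0.236 with an estimated correlation), including Trp53inp1 and Klf11 (-0.68 ± 0.13, adjusted p = 0.0264). Nop2, Utp14a, Trp53inp1 and Klf11 each lost their call without uncrushed vehicle replicate 2, or uncrushed DLKi replicate 3 or 4, among others (up to 0.125, 0.142, 0.0815 and 0.097). In crushed retina 0 ribosome biogenesis genes passed (5 adjusted over the list alone; 5.8e-05, adjusted p = 0.141 with an estimated correlation) and 0 FOXO-associated genes passed, but the list was lower there too (3 adjusted over the list alone; 0.00195, adjusted p = 0.194 with an estimated correlation). Ocular surface epithelial genes, a tissue outside the retina, were higher in crushed than in uncrushed DLKi retina in 11 of 16 (15 adjusted over the list alone; 1.42e-07, adjusted p = 0.203 with an estimated correlation) and in 0 of 16 against crushed vehicle (16 adjusted over the list alone; 1.49e-08, adjusted p = 0.194 with an estimated correlation). Crushed DLKi replicates 3 and 5 stood highest, with scores of 1.41 and 2.87, against -0.366, -1.29 and -2.67 in replicates 1, 2 and 4.

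A first hypothesis was that the inhibitor lowers the neuronal injury programme of crush but not the immune response. The injury lists were the axon injury, ATF4 target and immediate early lists, and the immune lists those of gliosis, microglia and interferon genes. The injury score minus the immune score differed by -0.435 in its crush effect between inhibitor and vehicle. The exact permutation p was 0.107 over the 56 splits of the 8 library pairs, which leaves the hypothesis open. ATF4 scores were alike in crushed retina (4.821 with inhibitor, 4.813 with vehicle) and differed in uncrushed retina (4.442 and 4.19). The immune scores rose more with the inhibitor, by 0.0208, 0.209 and 0.403, so -0.435 does not by itself measure a lowered injury programme. Each immune score started lower in uncrushed DLKi than in uncrushed vehicle retina. In crushed retina only the interferon score was higher with the inhibitor (2.738 against 2.561). A second hypothesis was that the inhibitor may keep the transcription factors of ganglion cells on without keeping the other markers. The mean of Pou4f1, Pou4f2, Pou4f3 and Isl2 minus that of 15 other markers was 0.905 higher with the inhibitor in crushed retina (exact permutation p = 0.0179, the smallest that 56 splits can give) and 0.0133 in uncrushed retina (p = 0.911, exact), and its crush effect was 0.892 higher (exact permutation p = 0.0179), but 3 of those 4 were themselves called in this comparison, so that test cannot speak for the group. Pou4f3, the 1 not called, differed from the other markers by 0.0513 (exact permutation p = 0.661), which decides nothing with a single gene. Whether ganglion cells survived in larger number was not measured.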
